A study of Homo sapiens with 12 samples.

How the data were processed

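Total RNA of HDLM-2 cells was extracted with Trizol, cleaned on RNeasy columns with DNase treatment and checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit for Illumina arrays, per the labels' protocols. The values used here are the authors' deposited processed intensity values, 1 per probe and array on a linear scale, for 48803 probes and 12 arrays. BeadStudio is named in the submitters' processing notes, with no version, and the normalization is not given in the sources used here. From the values, the sorted intensities of the 12 arrays differed by 0.052% at the median and by at most 1.09%, so a quantile normalization between arrays had been applied, and the lowest value was 109.7 on every array, so the background had not been subtracted to 0. A second deposited table of non-normalized signal has 24 columns, 12 of signal and 12 of detection p, whose names match no sample label, and it was not used here.

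Groups and the replicate letters A, B and C come from the sample titles, and the doses and the time from the series' design text and labels. The series title also speaks of in vivo treatment, which is not analysed here. Nothing says that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. No batch, slide or scan date is given in the sources used here.

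The plan made before the data were examined was to use detection p values for the background correction and for the filter. With the detection p values unmatched to samples, its written fallback was used instead: normexp background correction without control probes, offset 16, quantile normalization and log2. The filter on dim probes was set after the data were seen. On each array the mode of the signal (about 192) and the SD of the dim probes below it (about 20.5) gave a threshold at the upper 5% point of the corresponding normal distribution, about 225, and a probe was kept if it was above it on at least 3 of the 12 arrays. This kept 25119 probes. The platform annotation used here gave 1 gene symbol for 28098 probes, several for 13 and listed 20692 probes not at all. Of the named probes, 28059 had an Entrez identifier in the RefSeq gene table of GRCh38.p14, which served only for names and neighbouring genes. Each gene was represented by its passing probe with the highest mean log2 signal, 13549 genes in all, of which 3654 had more than 1 passing probe. Probes without a single symbol were tested apart.

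One limma (3.58.1, R 4.3.3) model with a mean per group was fitted to all 12 arrays, with lmFit, contrasts.fit and eBayes, 13.1 total degrees of freedom and a median residual SD of 0.18 on the log2 scale. The 7 contrasts were each single agent and the combination against the control, the combination against each single agent, sorafenib against perifosine, and the interaction. P values were adjusted by the Benjamini-Hochberg method within each contrast, and genes under an adjusted p of 0.05 were called. A gene beyond both single agents had to be called with the same sign in the combination against the control, against perifosine and against sorafenib. The moderated F test asked which genes differ among the 4 groups.

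The 31 gene lists were fixed before the data were examined. They cover the pathways of the drugs, stress responses, metabolism, cell cycle, cell death, Hodgkin cell molecules, markers of other cell types and housekeeping genes. Of 666 entries, 613 had a named probe and 566 were tested. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over 217 tests, and again with an estimated correlation and with fry, a self-contained test. Of 32 list calls, 22 held with an estimated correlation and 28 with fry.

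Named genes followed a rule fixed before the data were examined. They are the 10 largest rises and falls of each comparison with the control and the 5 largest of each other comparison, among genes called, changed at least 2-fold and with arrays that do not overlap between the groups. Up to 4 called members of each list were added, and TRIB3, DDIT3, CDKN1A, MCL1, CCND1, MYC and the drug targets could be named whatever their value. Symbols of unnamed loci were passed over.

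The fit was tested on simulated data with the means and spreads of the 13549 genes. In 10 simulations of sorafenib against control, 95.8% of genes planted at 2-fold, 46.2% at 1.5-fold and 3.4% at 1.25-fold were recovered, and 4.74% of calls were false. In 10 simulations of perifosine against control, a list shifted by 0.2 on the log2 scale had an unadjusted camera p under 0.05 in all 10. The list calls need an adjusted p, and these simulations held no correlation between genes. They therefore do not give the power of the list calls. In these simulations, single genes planted at 1.5-fold or less were missed more often than found with 3 arrays per group. The simulated noise was independent between arrays, with no arrays that deviate together, so recovery in the real data may be lower.

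Alternatives planned before the data were examined were the log2 of the deposited values without background correction, which is also the alternative of using the authors' processed values, a normexp offset of 50, cyclic loess, no filter, a strict filter (the upper 1% point, on all 3 arrays of a group, by signal in place of the planned detection p), all probes, eBayes with trend and robust, array weights, the compared groups alone, a replicate block, each array left out, and for the genes beyond both agents at least 1.5-fold in each test. Added after the data were seen were the signal-based filter, a fit without perifosine replicate B and sorafenib replicate C, and each drug's effect averaged over both levels of the other drug. Plots were drawn with matplotlib 3.10.9.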

Results

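Gene expression was measured in HDLM-2, an established human Hodgkin lymphoma cell line, after 24 h in culture with or without drug. Perifosine, an alkylphospholipid that inhibits AKT signalling, was used at 10 µM, and sorafenib, an inhibitor of RAF and of several receptor tyrosine kinases, at 5 µM. The 12 arrays fell into 4 groups of 3, namely untreated control, perifosine, sorafenib and the combination of both drugs. Each array gave a signal for 48803 probes, and between 21820 and 21938 of these lay above the background threshold on each array. The median deposited signal lay between 216.4 and 216.6 on the 12 arrays, because the deposited values already shared a common distribution, and the number of arrays limited the precision. Log2 signals correlated across genes at 0.988 to 0.994 within groups and at 0.987 to 0.994 between groups, and genes are not independent replicates. The comparisons asked what each drug did alone, what the combination did, and whether the combination went beyond the single agents. In what follows a log2 change is given with its standard error, the adjusted p is that of limma over 13549 genes, and every group has n = 3.

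After sorafenib alone, PSAT1, an enzyme of serine synthesis, rose by 1.09 ± 0.10 on the log2 scale (adjusted p = 0.00048), from a log2 signal of 11.89 ± 0.02 (SD) in the control to 12.99 ± 0.10 (SD). ASNS, which makes asparagine, rose by 0.95 ± 0.11 (adjusted p = 0.0019), CTH, which makes cysteine from cystathionine, by 1.04 ± 0.13 (adjusted p = 0.0019), and ASS1, which makes argininosuccinate, by 1.18 ± 0.21 (adjusted p = 0.021). VLDLR, a lipoprotein receptor, rose by 0.98 ± 0.11 (adjusted p = 0.0015). Of the 33 measured ATF4 and CHOP targets, the genes of the amino acid and integrated stress response, 7 rose, 0 fell and 26 did not pass, and 13 rose when adjusted over the list alone. The list as a whole was higher than other genes, with a median change of 0.32 and 25 of 33 members above 0 (camera, adjusted p = 7.91e-11; adjusted p = 0.0061 with an estimated correlation). DDIT3, which encodes CHOP, had a change of 0.53 ± 0.13 (adjusted p = 0.0931, and 0.0243 with array weights and 0.0441 without background correction, within a range of 0.0243 to 0.239 over the alternatives), and TRIB3, a pseudokinase that binds AKT, one of 0.00 ± 0.15 (adjusted p = 0.998).

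Other lists were lower after sorafenib. Of 22 ribosome biogenesis genes and MYC targets, 20 had a negative change, with a median of -0.25, 4 fell when adjusted over the list alone, and NOP16, a nucleolar protein of ribosome assembly, fell by 0.62 on the log2 scale (adjusted p = 0.046; camera, adjusted p = 2.49e-05, and adjusted p = 0.031 with an estimated correlation). All 16 measured heat shock protein genes had a negative change, with a median of -0.22, although 0 passed singly, also when adjusted over the list alone (camera, adjusted p = 0.00018; adjusted p = 0.031 with an estimated correlation). Among 18 genes of MAPK pathway output, the immediate-early transcription factor gene FOS fell by 0.86 (adjusted p = 0.0216; -0.48 without background correction), and 7 fell when adjusted over the list alone (camera, adjusted p = 0.00104; adjusted p = 0.037 with an estimated correlation). FOS was above background on 2 of 3 sorafenib arrays. RRM2, a subunit of ribonucleotide reductase, fell by 0.66 (adjusted p = 0.038) among 30 DNA replication genes (camera, adjusted p = 0.0051; adjusted p = 0.21 with an estimated correlation). OAS3, an antiviral oligoadenylate synthetase, rose by 0.63 ± 0.13 (adjusted p = 0.039) among 24 interferon-stimulated genes, whose median change was 0.16 and of which 6 rose when adjusted over the list alone (camera, adjusted p = 0.0094; adjusted p = 0.062 with an estimated correlation). The other passing probe of OAS3 had a change of 0.03. With 1 array left out, the calls of OAS3, RRM2 and NOP16 ended in 10, 9 and 9 of 12 fits (adjusted p up to 0.155, 0.154 and 0.148). The other 25 of the 31 lists did not pass, among them the housekeeping genes and the markers of B, T and myeloid cells and of fibroblasts and endothelium.

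Genes outside the fixed lists also changed at least 2-fold with sorafenib. INHBE, an activin subunit, rose by 1.10 ± 0.21, CYP4Z1, a cytochrome P450, by 1.10 ± 0.16, ASB9, a component of ubiquitin ligases, by 1.03 ± 0.12, CAV1, the main caveolar coat protein, by 1.01 ± 0.13, MAP2K6, a kinase upstream of p38, by 1.01 ± 0.18, with 1 of 3 control arrays above background, and SERPINI1, a serine protease inhibitor, by 1.04 ± 0.18, while its other passing probe had a change of 0.28. C4BPB, a chain of the C4b-binding protein, rose by 1.09 ± 0.19, while its other passing probe had a change of 0.14. Other passing probes of CYP4Z1 had changes of 0.86, 0.85 and 0.48. MIR503HG, a non-coding host transcript of a microRNA, fell by 1.64 ± 0.24 on the log2 scale, and the linker histone gene H1-2 fell by 1.24 ± 0.15. The keratin-associated protein genes KRTAP9-3, KRTAP9-4 and KRTAP9-8 fell by 1.57 ± 0.17, 1.26 ± 0.14 and 1.10 ± 0.12, and other passing probes of KRTAP9-4 and KRTAP9-8 had changes of -0.80 and -0.41. Without background correction the changes of MAP2K6 and KRTAP9-8 were 0.49 and -0.65, and that of KRTAP9-3 was also over 1.5 times smaller. KRTAP9-3 was above background on 2 of 3 sorafenib arrays. These KRTAP9 genes are near-identical copies, so which of them fell is uncertain. The adjusted p of the genes in this paragraph lay between 0.0015 for KRTAP9-3 and 0.026 for INHBE.

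In all, 111 of 13549 genes changed with sorafenib, 74 higher and 37 lower, and 15 of them at least 2-fold, 10 higher and 5 lower. The count was 72 without perifosine replicate B and sorafenib replicate C, a pair of arrays that deviated together. It lay between 37 and 59 when any single control or sorafenib array was left out, with the lowest value without control replicate C, and was 167 without perifosine replicate B. Of 21 named calls, 12 held whichever array was left out, namely PSAT1, ASNS, CTH, VLDLR, ASB9, CAV1, CYP4Z1, H1-2, MIR503HG, KRTAP9-3, KRTAP9-4 and KRTAP9-8. The 9 that did not were ASS1, C4BPB, FOS, INHBE, MAP2K6, SERPINI1, NOP16, OAS3 and RRM2.

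Perifosine alone changed 0 of 13549 genes by limma. The smallest adjusted p was 0.991, and 543 genes had an unadjusted p under 0.05, where chance gives 677. The genes of sterol synthesis and uptake were higher as a list, with 17 of 20 members above 0 and a median change of 0.16 (camera, adjusted p = 0.0036; adjusted p = 0.046 with an estimated correlation). None of the 20 passed, also when adjusted over the list alone (0 rose), and the largest value was that of LSS, lanosterol synthase, at 0.33 ± 0.11, named after its value was seen. The list had an adjusted p of 0.061 without perifosine replicate B, and of 0.1004 without it and sorafenib replicate C. The other 30 lists did not pass, and the nearest were the NF-kB targets, with a median of -0.15 (adjusted p = 0.080). Of the genes around the drug's target, AKT1 had a change of 0.02 ± 0.13, AKT2 of -0.41 ± 0.22, PIK3CD of 0.20 ± 0.14 and MTOR of -0.05 ± 0.12, each with an adjusted p of 0.991 or more. TRIB3 had a change of -0.28 ± 0.15 (adjusted p = 0.991). Its log2 signal was lowest on perifosine replicate B, at 8.88, against 9.50 and 9.41 on replicates A and C.

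With the combination against the control, PSAT1 rose by 1.16 ± 0.10 (adjusted p = 0.00023), ASS1 by 1.29 ± 0.21 (adjusted p = 0.013), CTH by 1.02 ± 0.13 (adjusted p = 0.0025), ASNS by 0.99 ± 0.11 and VLDLR by 0.94 ± 0.11 (both adjusted p = 0.0018). Of the 33 ATF4 and CHOP targets, 6 rose, 0 fell and 27 did not pass, and 14 rose when adjusted over the list alone, with 30 of 33 members above 0 and a median of 0.35 (camera, adjusted p = 2.36e-15; adjusted p = 0.0061 with an estimated correlation). AARS1, which charges tRNA with alanine, rose by 0.58 ± 0.10 (adjusted p = 0.017) among 18 cytosolic aminoacyl-tRNA synthetases, of which 6 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0175; adjusted p = 0.261 with an estimated correlation; adjusted p = 0.0588 without control replicate B). DDIT3 had a change of 0.49 ± 0.13 (adjusted p = 0.15) and TRIB3 one of 0.35 ± 0.15 (adjusted p = 0.38).

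Against the control, the combination also lowered ribosome biogenesis genes and MYC targets (median -0.25, 20 of 22 below 0, adjusted p = 1.23e-06), DNA replication genes (median -0.19, 27 of 30 below 0, adjusted p = 1.11e-05), heat shock protein genes (median -0.18, 15 of 16 below 0, adjusted p = 9.83e-05) and genes of MAPK pathway output (median -0.22, 12 of 18 below 0, adjusted p = 0.00085) as lists. With an estimated correlation these had adjusted p values of 0.031, 0.044, 0.031 and 0.036. FOS fell by 0.88 ± 0.15 (adjusted p = 0.0168; -0.49 without background correction) and was the single member of these lists to pass, while 2, 1, 0 and 5 members fell when adjusted over the list alone. FOS was above background on 2 of 3 combination arrays. Interferon-stimulated genes were higher (median 0.15, adjusted p = 0.00021; adjusted p = 0.031 with an estimated correlation), and ISG20, an antiviral exonuclease, rose by 0.65 ± 0.10 (adjusted p = 0.013). Sterol genes were higher with a median of 0.22 and 17 of 20 members above 0 (adjusted p = 0.0075; adjusted p = 0.062 with an estimated correlation). Cytokines, chemokines and surface molecules of Hodgkin cells were higher (adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation), as were the metallothioneins (adjusted p = 0.041; adjusted p = 0.52 with an estimated correlation), with 0 members passing in either. Adjusted over the list alone, 5 rose and 1 fell of the former and 3 rose and 0 fell of the latter. The Hodgkin cell list had an adjusted p of 0.0637 without control replicate A, and the metallothioneins did not pass in 10 of the 12 fits that left out 1 array.

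CXCL8, the chemokine interleukin-8, fell by 0.79 ± 0.11 (adjusted p = 0.0053), TNFRSF10A, a receptor for the death ligand TRAIL, by 0.58 ± 0.10 (adjusted p = 0.017) and the hypoxia-responsive gene ANKRD37 by 0.58 ± 0.11 (adjusted p = 0.031), all with the combination against the control. CXCL8 was above background on 1 of 3 combination arrays, its other passing probe had a change of -0.40, and its change was -0.42 without background correction. The lists that hold these genes, the NF-kB targets, pro-apoptotic genes and glycolysis and hypoxia genes, did not pass (adjusted p = 0.985, 0.985 and 0.31). ULBP1, a ligand of the NKG2D receptor of natural killer cells, rose by 1.01 ± 0.11 (adjusted p = 0.00182), and the signal of SNTB1, a syntrophin, rose from 980 in the control to 1841 (adjusted p = 0.000888). INHBE rose by 1.16 ± 0.21 and C4BPB by 1.16 ± 0.19, whose other passing probe had a change of 0.10. KRTAP9-4 fell by 1.43 ± 0.14, MIR503HG by 1.41 ± 0.24, KRTAP1-5 by 1.04 ± 0.18 and KRTAP9-3 by 1.02 ± 0.17. The other passing probe of KRTAP9-4 had a change of -0.56. KRTAP1-5 was above background on 1 of 3 combination arrays and had a change of -0.51 without background correction. MCL1, an anti-apoptotic gene, had a change of -0.41 ± 0.12 (adjusted p = 0.18; -0.56 for another passing probe), CDKN1A one of 0.02 ± 0.13 (-0.22 for another passing probe) and MYC one of 0.02 ± 0.14. CCND1 was too dim to be tested.

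In all, 85 genes changed against the control with the combination, 64 higher and 21 lower, and 11 at least 2-fold. The count was 137 without perifosine replicate B and sorafenib replicate C, and it lay between 34 and 50 when any single control or combination array was left out, with the lowest value without combination replicate C. Of 19 named calls, 8 held whichever array was left out, namely PSAT1, ASNS, CTH, VLDLR, CXCL8, ULBP1, SNTB1 and KRTAP9-4. The call of ANKRD37 ended in 9 of the 12 fits (adjusted p up to 0.162), and those of AARS1 and TNFRSF10A in 6.

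**Figure D1:**
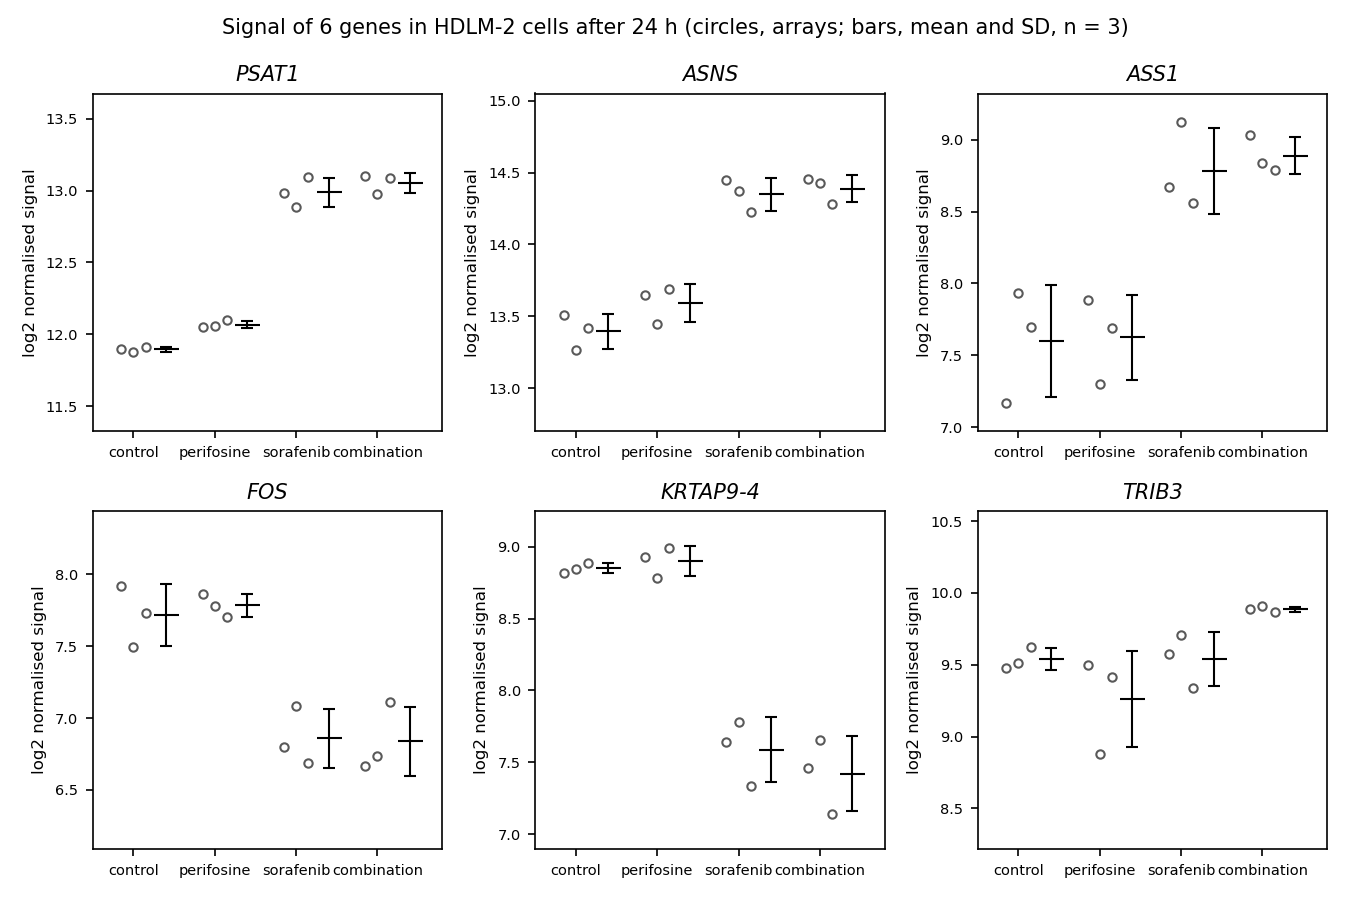
Log2 normalised signal (vertical axis) of 6 genes in the 4 groups (horizontal axis), with 1 circle per array and bars for the mean and SD (n = 3). For PSAT1, ASNS, ASS1, FOS and KRTAP9-4 the sorafenib and combination arrays lie together and apart from the control and perifosine arrays, and for TRIB3 no comparison passed the threshold.

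What sorafenib added to perifosine was measured on arrays that the comparison of sorafenib with the control did not use. CYP4Z1 rose by 1.30 ± 0.16 (adjusted p = 0.0029), ASS1 by 1.26 ± 0.21, C4BPB by 1.16 ± 0.19, INHBE by 1.15 ± 0.21 and GPER1, a membrane oestrogen receptor, by 1.09 ± 0.15. With the combination against the control this probe of GPER1 had a change of 0.75, and its other passing probes had 0.80 and -0.02. PSAT1 rose by 0.99 ± 0.10 (adjusted p = 0.00089), ASNS by 0.80 ± 0.11, VLDLR by 0.75 ± 0.11 and MTHFD2, a mitochondrial folate enzyme, by 0.53 ± 0.10, and 5 of 33 ATF4 and CHOP targets rose (15 when adjusted over the list alone; camera, adjusted p = 4.32e-12; adjusted p = 0.0061 with an estimated correlation). Among 18 genes of MAPK pathway output, EGR1, an immediate-early transcription factor, fell by 1.15 ± 0.20, FOS by 0.94 ± 0.15 and DUSP5, a phosphatase of ERK, by 0.52 ± 0.10 (list adjusted p = 0.00208; adjusted p = 0.0437 with an estimated correlation). EGR1 was above background on 1 of 3 combination arrays and FOS on 2 of 3, and without background correction the changes of EGR1 and FOS were -0.63 and -0.53. IFIT3 rose by 0.81 ± 0.13 and ISG20 by 0.75 ± 0.10 among the interferon-stimulated genes (adjusted p = 0.00052; adjusted p = 0.031 with an estimated correlation). With the combination against the control this probe of IFIT3 had a change of 0.58, and its other passing probes had 0.57 and 0.17. CCL17, the chemokine TARC of Hodgkin cells, rose by 0.66 ± 0.12 (adjusted p = 0.027), while its list had an adjusted p of 0.0409 and an adjusted p = 0.357 with an estimated correlation, and did not pass without combination replicate A or B or perifosine replicate A or B (adjusted p up to 0.191).

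Against perifosine, the lists of DNA replication (median -0.16), ribosome biogenesis and MYC targets (median -0.25) and heat shock proteins (median -0.18) were lower, with adjusted p of 2.49e-05, 4.46e-05 and 0.00038. With an estimated correlation these were adjusted p = 0.046, 0.031 and 0.031. The aminoacyl-tRNA synthetases were higher (adjusted p = 0.0196; adjusted p = 0.261 with an estimated correlation; adjusted p = 0.136 without perifosine replicate B). TRAF1, an NF-kB target that Hodgkin cells express, rose by 0.65 ± 0.13 (adjusted p = 0.044) and FCER2, the surface molecule CD23, by 0.62 ± 0.13 (adjusted p = 0.048). Both calls ended in 11 of the 12 fits that left out 1 array (adjusted p up to 0.163 and 0.214). CXCL8 fell by 0.63 ± 0.11 and TNFRSF10A by 0.58 ± 0.10. Without background correction CXCL8 did not pass (-0.32, adjusted p = 0.0674), and the change of KRTAP9-8 was -0.67. KRTAP9-4 fell by 1.48 ± 0.14, MIR503HG by 1.31 ± 0.24 and KRTAP9-8 by 1.07 ± 0.12, and KRTAP9-3 fell 2.38-fold (adjusted p = 0.00635). TRIB3 had a change of 0.62 ± 0.15 (adjusted p = 0.095), with a low log2 signal on perifosine replicate B (8.88, against 9.50 and 9.41 on replicates A and C). In all, 97 genes changed, 75 higher and 22 lower, 12 of them at least 2-fold. The count lay between 24 and 52 when any single combination or perifosine array was left out, and 9 of 23 named calls held whichever array was left out, namely PSAT1, ASNS, VLDLR, CYP4Z1, GPER1, ISG20, KRTAP9-3, KRTAP9-4 and KRTAP9-8. The call of MTHFD2 ended in 9 of the 12 fits (adjusted p up to 0.170).

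Of the 111 genes that changed with sorafenib against the control, 106 had the same sign in the combination against perifosine, and 49 were called in both, 36 higher and 13 lower, where independent lists would share 0.41 and 0.06. The median ratio of the second change to the first was 0.72 over the 111 genes. Because these genes were chosen by the first change, that change tends to be overstated, and the ratio does not show a weaker effect beside perifosine. These comparisons share no array, though the per-gene spread was estimated once over all 12 arrays. Across all genes the log2 changes correlated at r = 0.26 (0.35 without perifosine replicate B and sorafenib replicate C), and genes are not independent replicates.

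What perifosine added to sorafenib was 0 genes by limma, with a smallest adjusted p of 0.608, and 818 genes at an unadjusted p under 0.05 where chance gives 677. CDK inhibitors and growth arrest genes were higher as a list, with 14 of 16 members above 0 and a median of 0.12 (camera, adjusted p = 0.017; adjusted p = 0.29 with an estimated correlation), and 0 of the 16 passed, over all genes or adjusted over the list alone. That list lost its call without combination replicate B (adjusted p = 0.18) and also without sorafenib replicate A. It also lost its call with fry, and 0 lists passed when adjusted within this comparison alone. TRIB3 had a change of 0.35 ± 0.15 (adjusted p = 0.815), with its lowest sorafenib log2 signal on replicate C (9.34, against 9.57 and 9.71 on replicates A and B). Sterol genes had a median change of 0.06 (adjusted p = 0.317). Across all genes, the changes with perifosine beside sorafenib and alone, on different arrays, correlated at r = -0.25. Without perifosine replicate B and sorafenib replicate C, r was -0.11. The deviations of those arrays correlated at 0.39, and they enter these comparisons with opposite signs, which lowers r. With 0 genes called in either comparison, an opposite action of perifosine beside sorafenib cannot be read from this r.

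The interaction of the drugs, the departure of the combination from the sum of the single-agent log2 changes, passed for 0 genes by limma (smallest adjusted p = 0.379) and for 0 of 31 lists. At an unadjusted p under 0.05 there were 1028 genes, where chance gives 677. Perifosine replicate B and sorafenib replicate C, which deviated together, both enter the interaction with a negative sign, so their shared deviation adds up in it. For TRIB3 the interaction was 0.63 ± 0.21 on the log2 scale (adjusted p = 0.60). Its signal was the lowest of the group on perifosine replicate B (8.88) and on sorafenib replicate C (9.34), which raises this value. No gene was called in the same direction against the control, against perifosine and against sorafenib, and 114 genes met all these tests at an unadjusted p under 0.05. How many chance gives was not computed for these tests, which share arrays. These counts do not show that the drugs act additively, since changes smaller than the spread between arrays would not pass.

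The single agents set against each other gave 60 genes, 45 higher with sorafenib and 15 lower. PSAT1 was higher with sorafenib by 0.92 ± 0.10, VLDLR by 0.79 ± 0.11, ASNS by 0.76 ± 0.11 and CYP4Z1 by 1.43 ± 0.16, and IFIT3 was higher by 0.78 ± 0.13 and CCL17 by 0.63 ± 0.12. MAP2K6 was not above background on any perifosine array and was higher with sorafenib (adjusted p = 0.0114), with mean deposited signals of 193.1 and 286.7, and did not pass without perifosine replicate B and sorafenib replicate C (adjusted p = 0.0704). FOS fell by 0.93 ± 0.15 and DUSP5 by 0.52 ± 0.10, and KRTAP9-3, at -1.79 ± 0.17, had the largest fall among the named genes. Without background correction the changes of FOS and KRTAP9-3 were -0.53 and -1.17, and each was above background on 2 of 3 sorafenib arrays. The ATF4 and CHOP targets were higher (3 of 33 rose, adjusted p = 5.00e-11; adjusted p = 0.0061 with an estimated correlation), as were the interferon-stimulated genes (adjusted p = 0.0038; adjusted p = 0.046 with an estimated correlation). Ribosome biogenesis genes, heat shock protein genes and MAPK output were lower (adjusted p = 2.67e-05, 4.46e-05 and 0.00027; each adjusted p = 0.031 with an estimated correlation), and so were DNA replication genes (adjusted p = 0.00085; adjusted p = 0.12 with an estimated correlation). The count of genes was 27 without perifosine replicate B and sorafenib replicate C, 11 and 29 without perifosine replicates A and C, and between 13 and 39 when any single sorafenib array was left out. Of 17 named calls, 6 held whichever array was left out, namely PSAT1, VLDLR, CYP4Z1, KRTAP9-3, KRTAP9-4 and KRTAP9-8. Those of CCL17 and DUSP5 ended in 11 of the 12 fits (adjusted p up to 0.1997 and 0.157).

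Over all 4 groups, 130 genes differed by the limma F test. The count lay between 58 and 83 without any single control or combination array, perifosine replicate A or sorafenib replicate A.

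**Figure D2:**
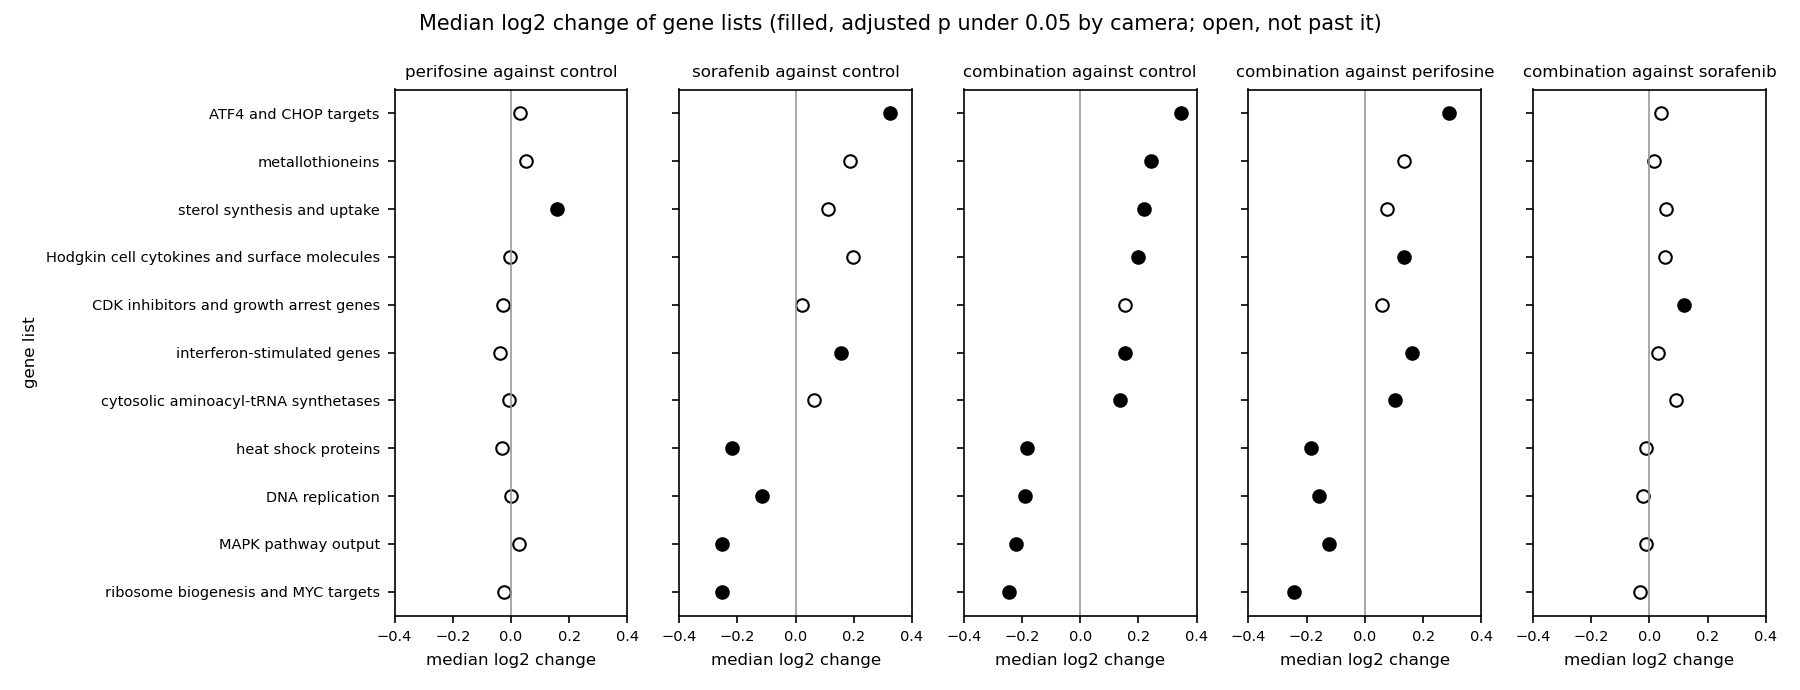
Median log2 change (horizontal axis) of the gene lists that passed in at least 1 of the 5 comparisons shown, one panel per comparison and one row per list, with filled circles for an adjusted p under 0.05 by camera with a preset correlation. The ATF4 and CHOP targets lie at 0.32, 0.35 and 0.29 in the comparisons that add sorafenib, and at 0.03 and 0.04 in those that add perifosine.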

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

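The tests of a swap of arrays and of the KRTAP genes, the test of the sterol list beside sorafenib, and the averaged effects of each drug were chosen only after the result was seen; the counts over other splits, the test at background and that without perifosine replicate B were not.

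Probes that the platform annotation used here does not name carried signal outside the comparisons. Among 6665 such probes above background, 23 changed with sorafenib against the control, 15 higher and 8 lower, and 15 changed with the combination against the control, 11 higher and 4 lower. The largest change was that of probe ILMN_2376194, which rose by 1.61 ± 0.21 (SE, limma adjusted p = 0.0058) with sorafenib and by 1.76 ± 0.21 (adjusted p = 0.0040) with the combination.

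Perifosine replicate B and sorafenib replicate C deviated from their group means together, with a correlation across genes of 0.39, the highest among the 54 pairs of arrays from different groups, and array weights of 0.37 and 0.47. A swap of the arrays is argued against, since the score of 137 genes called in the combination against the control, in a fit that held neither array, was higher on sorafenib replicate C than on perifosine replicate B by 0.54, against a largest range within a group of 0.039. A technical difference that reaches probes at background cannot be told apart from one that does not: over 16823 probes below the threshold on all arrays the correlation was 0.033, under the bound of 0.05 set beforehand, but that bound was too high, since the other pairs ran from -0.030 to 0.017. RNA quality and a shared culture history stay open and were not tested. No biological explanation was tested, since the arrays belong to different groups.

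Of 31 keratin-associated protein genes, 6 fell in the averaged sorafenib effect. Of 5 KRTAP genes called lower with sorafenib against the control, 4 were also called lower in the combination against perifosine, on other arrays. These were KRTAP1-5, KRTAP9-3, KRTAP9-4 and KRTAP9-8, with control signals from 1.30 to 2.58 times the threshold. The KRTAP9 probes may read 1 transcript, so the repeats may not be independent. The count therefore cannot decide on noise of signals close to background. KRTAP17-1, at 38.0 times the threshold, is far from background. It changed by -0.56 with sorafenib and by -0.42 in the combination against perifosine (limma adjusted p = 0.023 and 0.092). Probes of near-identical KRTAP9 genes that read 1 transcript cannot be told apart from separate changes, because 4 of the 6 genes lower in the averaged sorafenib effect are KRTAP9 copies and 2, KRTAP1-5 and KRTAP17-1, are not, and probe sequences were not used here. An effect of sorafenib on 1 or several transcripts stays open, as does a shift of all neighbouring genes on chromosome 17, with a median of -0.099 over the 6 tested neighbours (the 10.1 percentile of 13394 windows). All 6 neighbours are keratin-associated protein genes themselves, so no other kind of gene was among them. Of these, KRTAP4-1, at 2.44 times the threshold, had a change of -0.26 ± 0.09 (adjusted p = 0.136), and the others had control signals between 0.961 and 1.07 times the threshold.

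The sterol genes were higher with perifosine by a median of 0.16. A deviation of perifosine replicate B may contribute, but without it the median was 0.154, with 13 of 20 members above 0 in place of 17, and the list's adjusted p was 0.0613. Whether an effect of perifosine is also present beside sorafenib stays open, since the unadjusted camera p there was 0.091 with a median of 0.058. No single member passed.

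With 10 splits of 6 arrays no share under 0.05 can be reached. Counting the real split, 10 of 10 splits gave as many genes for perifosine against the control (0, highest other 0) and for the combination against sorafenib (0, highest other 0). For each other comparison of groups, 1 of 10 splits gave as many genes, the real one, with 111 genes for sorafenib against the control (highest other 0), 85 for the combination against the control (highest other 0), 97 for the combination against perifosine (highest other 0) and 60 for sorafenib against perifosine (highest other 1). For lists adjusted within the comparison, the real split and highest other were 1 and 0 for perifosine, 6 and 3 for sorafenib, 12 and 4 for the combination against the control, 9 and 2 against perifosine, 0 and 0 against sorafenib (10 of 10 splits), and 6 and 2 for sorafenib against perifosine.

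Over 100 splits of the 12 arrays into 4 groups, 1, the real one, gave as many genes in the F test as the 130 found (highest other 98). A random grouping of these arrays is argued against there, though splits cannot tell a drug effect from a difference between cultures. For the interaction 100 of 100 splits gave at least the 0 genes and 0 lists found (highest others 470 and 11). Such a count is reached by any split, so nothing is concluded from it. Splits of all 12 arrays can carry the sorafenib effect into this contrast, and which split called 470 genes was not examined. For genes beyond both agents, 100 of 100 splits gave at least the 0 found (highest other 0). Within the levels of the other drug, 1 of 100 splits, the real one, reached the 512 genes of the averaged sorafenib effect (highest other 6). This argues against a random grouping, though that contrast was chosen after the result was seen. For the averaged perifosine effect, 100 of 100 splits reached the 0 genes found (highest other 1).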

How the results depend on the processing

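The fit without perifosine replicate B and sorafenib replicate C was chosen only after the result was seen. The counts of 0 for perifosine against control, combination against sorafenib, the interaction and genes beyond both agents stayed 0 under every alternative run. The other counts moved, and the cause was not tested. In the order sorafenib against control, combination against control, combination against perifosine, sorafenib against perifosine and the F test, the counts of 111, 85, 97, 60 and 130 became 238, 209, 289, 141 and 300 with array weights, 251, 203, 247, 126 and 287 without background correction, 242, 187, 249, 123 and 269 with trend and robust, 200, 157, 147, 95 and 207 with the strict filter, and 40, 55, 41, 35 and 64 with no filter. With only the compared groups the first 4 were 23, 52, 23 and 9. An offset of 50 gave 169 for sorafenib against control. The averaged sorafenib effect, 512 genes, had 973 with array weights, 815 without background correction and 247 with no filter. Without both arrays that deviate together they were 72, 137 and, for sorafenib against perifosine, 27. No pairing of the samples by letter was seen (2 of 18 same-letter pairs had a correlation of deviations over 0.1, from -0.24 to 0.20). The letters may still mark a shared culture or day. The replicate block gave 48, 54, 45, 30 and 67.

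Leaving out single arrays gave ranges of 37 to 167, 34 to 116, 24 to 100, 11 to 58 and 58 to 120. For sorafenib against control the counts were 40, 45 and 37 without control replicates A, B and C, 59, 45 and 53 without sorafenib A, B and C, and 167 without perifosine B. For combination against control they were 38, 50 and 41 without control A, B and C, and 44, 45 and 34 without combination A, B and C. Against perifosine they were 33, 29 and 24 without combination A, B and C, and 32, 52 and 49 without perifosine A, B and C. For sorafenib against perifosine they were 11 and 29 without perifosine A and C, and 16, 13 and 39 without sorafenib A, B and C. For the F test they were 67, 76 and 75 without control A, B and C, 83, 83 and 58 without combination A, B and C, 71 without perifosine A and 83 without sorafenib A. Calls of named genes were lost for 26 of 80 with no filter, 40 of 80 with only the compared groups, 29 of 80 with the replicate block, 21 of 80 without both deviating arrays and 1 of 80 without background correction, and DDIT3 gained a call for sorafenib against control with array weights and without background correction. Of 32 list calls, 10 were lost with an estimated correlation, 4 with fry, 4 without both deviating arrays, 3 with array weights, 2 with the replicate block, 2 with the strict filter, 1 with no filter and 1 with only the compared groups. Those lost without both arrays were the sterol genes with perifosine (adjusted p = 0.1004), the metallothioneins with the combination against control, and, against perifosine, the Hodgkin cell molecules and the aminoacyl-tRNA synthetases. Without background correction 15 of 80 called changes were over 1.5 times smaller; 0 of 80 moved by so much under any other alternative, single arrays left out not counted. Of the calls of named genes, 703 of 960 held with 1 array left out, and of the list calls 364 of 384; none of the named genes or lists changed sign where it was called. Median scaling was not run, as the arrays already share a distribution, nor a slide block, as no slide is given. Genes whose signal lies near the threshold are limited by background.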

Other observations

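All of the following was chosen only after the result was seen, as the effect of each drug averaged over both levels of the other drug, which sets 6 arrays against 6. For the averaged effects, only the counts of called genes were redone with arrays left out and under the processing alternatives. The single genes and lists named for them were not, apart from the estimated correlation of the lists.

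Averaged over both backgrounds, sorafenib changed 512 of 13549 genes by limma, 349 higher and 163 lower, and 462 without perifosine replicate B and sorafenib replicate C. Without single arrays the count was 273, 305 and 306 for control replicates A, B and C, 312 and 332 for perifosine replicates A and C, 287 and 298 for sorafenib replicates A and B, and 294 and 283 for combination replicates A and C. Of the 33 ATF4 and CHOP targets, 13 rose, among them the transcription factor genes ATF4 (0.37 ± 0.08, SE), ATF5 (0.55 ± 0.13), DDIT3 (0.49 ± 0.09) and CEBPG (0.43 ± 0.08), the glutathione-degrading enzyme gene CHAC1 (0.56 ± 0.13) and the glutamine transporter gene SLC1A5 (0.44 ± 0.08), all on the log2 scale (camera, adjusted p = 1.37e-15 over 62 tests; adjusted p = 0.00192 with an estimated correlation). The aminoacyl-tRNA synthetase genes AARS1, WARS1 and GARS1 rose by 0.40, 0.39 and 0.38, while their list did not pass (adjusted p = 0.0596). The ERK-responsive genes FOS, EGR1, ETV5, DUSP5 and FOSL1 fell by 0.90, 0.87, 0.58, 0.42 and 0.38 on the log2 scale (list adjusted p = 9.25e-05; adjusted p = 0.0161 with an estimated correlation). IFIT3, MX2, ISG20, OAS3 and RIGI, interferon-stimulated genes, rose by 0.68, 0.61, 0.60, 0.45 and 0.44 (list adjusted p = 0.000136; adjusted p = 0.0161 with an estimated correlation). Of the Hodgkin cell molecules, CCL17, TNFRSF9, FSCN1 and CD80 rose by 0.54, 0.47, 0.43 and 0.34, while CD274, which encodes the checkpoint ligand PD-L1, fell by 0.36 ± 0.08 (adjusted p = 0.0199), and their list had an adjusted p of 0.0312, and an adjusted p = 0.270 with an estimated correlation. Of the 23 pro-apoptotic genes, PMAIP1, which encodes NOXA, rose by 0.58 ± 0.12 (adjusted p = 0.017), while TNFRSF10A, a TRAIL receptor gene, fell by 0.42 ± 0.07 (adjusted p = 0.0068), and their list did not pass (adjusted p = 0.958).

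Among 48 genes with symbols of the histone series H1-, H2AC, H2BC, H3C and H4C, gathered after histone genes had been seen among those that fell and so without an independent test, 15 fell and 0 rose in the averaged sorafenib effect, with a median of -0.28 and 41 below 0. Single comparisons, on different arrays, had 4 that fell for sorafenib against the control (median -0.37, 42 of 48 below 0) and 1 that fell for the combination against perifosine (median -0.21, 40 of 48 below 0), with 0 that rose in either by limma. Histone genes with other symbols were not counted, among them H2AJ, which fell by 0.61 ± 0.12 (adjusted p = 0.0152) in the averaged effect. Of the 48, H1-2, H3C10 and H2AC18 fell by 0.87 ± 0.10, 0.64 ± 0.10 and 0.61 ± 0.09. Many histone genes of a type are similar and probe sequences were not used here, so which of them fell is uncertain. How fully the labelling captured histone transcripts was not tested, so these are changes of array signal and may not be those of total histone mRNA. The H1 genes went different ways, with H1-3 at -0.34 and H1-1, H1-7 and H1-10 at 0.16, 0.30 and 0.07. Averaged over both backgrounds, perifosine changed 0 genes by limma, with 448 at an unadjusted p under 0.05, and the sterol genes were higher with a median of 0.094 (camera, adjusted p = 0.00024 over 62 tests; adjusted p = 0.019 with an estimated correlation). The ATF4 and CHOP targets (median 0.051, adjusted p = 0.0297; adjusted p = 0.165 with an estimated correlation) and the CDK inhibitors and growth arrest genes (median 0.064, adjusted p = 0.0414; adjusted p = 0.305 with an estimated correlation) were also higher with perifosine, with 0 members passing in either.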
